A study of Homo sapiens with 12 samples.

How the data were processed

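The 12 libraries come from HT-1080 cells with an empty pCDH vector or with an ATF3 vector, made stable by lentivirus and puromycin, and given APR-246 or vehicle, with 3 libraries in each of 4 groups. The labels give no dose or time for APR-246, put every library in batch 1, and describe poly(A) RNA extracted with TRIzol and a strand-marking (dUTP) library. Whether the counting used strand is not given in the sources used here, so overlapping and antisense genes are uncertain. The series design calls the Control cells wild type, while the sample labels give them a vector, and the sample labels were followed.

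The submitters' processing notes name fastp, HISAT2, StringTie, edgeR and the genome build GRCh38, without versions. The deposited table holds, per gene and library, FPKM (fragments scaled by the authors to transcript length and library total) and estimated counts. The deposited estimated counts are whole numbers that were not scaled between libraries. They are not a plain tally of fragments: the value 4 occurs 1.48 times, 8 1.31 times and 12 1.22 times as often as its neighbours, so the totals of 56900740 to 73664715 give the relative depth of the libraries and not their number of fragments. The table has 35308 genes, and no column of per-sample values was left unused.

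Levels are given as deposited FPKM. Tests used the estimated counts in edgeR 4.0.16 (R 4.3.3): filterByExpr left 19970 genes, TMM scaled the libraries, and a quasi-likelihood model with 4 group means on all 12 libraries tested 4 comparisons of groups and the interaction, 2-sided, with Benjamini-Hochberg adjustment within each and a threshold of 0.05. Each adjusted p of a single gene is from that edgeR test, and SE is the log2 fold change divided by the root of its F value. The plan written before the data were examined called for limma with trend on log2 of FPKM plus 1. It named edgeR instead if the table held raw counts per library. The deposited counts are estimates, so it is uncertain whether that condition was met. The planned limma run is therefore also given among the alternatives. That limma run called 2687 genes higher and 5016 lower for APR-246 against Control, against 4465 and 4556 with edgeR. The common biological coefficient of variation was 0.172.

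Gene lists, 21 in all, were fixed before the data were examined. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and at an estimated correlation where at least 5 members were tested, which left out the metallothioneins. The named genes were also set by a rule fixed then: the 6 largest rises and falls per comparison among called genes with a mean of at least 5 FPKM and no overlap between the groups' libraries, up to 2 members of each list, 8 genes named in advance, and for the interaction the 5 largest values in each direction. ATF3, SLC7A11, GPX4, CHAC1, HMOX1, CDKN1A, PTGS2 and TFRC are the 8. AARS1, SLC6A9, CRYAB and ALOX12B fall outside the rule and were chosen after their values were seen. The correlation of fold changes across genes was compared, where Control libraries are shared, with 20 simulations of unchanged groups.

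The edgeR test was tested on simulated data of the same size and spread. It held 22 or 23 changed genes per size of change, so its shares are coarse. For genes changed by log2 1 it recovered 45.5% in a comparison like APR-246 against Control, 59.1% in the comparison like ATF3-OE against Control and 27.3% for an interaction, and 6.25%, 9.3% and 10.7% of the calls were false. Changes of log2 0.5 were recovered in 26.1%, 43.5% and 22.7% of cases, so a gene that did not pass may still differ by that much. The simulation changed a far smaller share of genes than was called for APR-246 against Control (45.2%) or ATF3-OE against Control (13.3%). The adjustment depends on that share, so the simulated shares of recovered and false calls do not carry over to these comparisons.

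Alternatives planned in advance were DESeq2 1.42.0 (its size factors, and its Wald test), no filter on low counts, a term for the replicate number, only the 2 groups compared, a minimum absolute log2 fold change of 1, each library left out in turn, and limma on FPKM with a pseudocount of 0.1 in place of 1, no filter, a minimum of 5 FPKM in place of 1, median-ratio scaling, quantile normalization or no trend. Limma with trend on log2 of FPKM plus 1 was the plan's main test unless the table held raw counts. It became an alternative after the data were seen. Added then were counts divided by 4, and correlations on a fixed set of genes when a library is left out. GC content and length came from the longest reference transcript, found for 94.3% of tested genes.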

Results

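HT-1080 is an established human fibrosarcoma cell line. APR-246 (eprenetapopt) is a small molecule, developed as a reactivator of mutant p53, whose breakdown product binds thiols such as glutathione. ATF3 is a stress-induced transcription factor of the ATF/CREB family, and SLC7A11 is the transport subunit of the cystine/glutamate exchanger that supplies cysteine for glutathione. Ferroptosis is cell death through iron-dependent lipid peroxidation. The series asks how a raised level of ATF3 bears on the response of these cells to APR-246. Cells carrying an empty lentiviral vector or an ATF3 vector were given vehicle or APR-246, which makes 4 groups of 3 libraries: Control, APR-246, ATF3-OE and ATF3-OE+APR-246.

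The library totals lay between 56900740 and 73664715 estimated counts, and 19970 genes were tested. Across genes, replicates of a group correlated at r = 0.976 to 0.979 on the log2 scale. The first principal component (34.8% of the variance) separated libraries with APR-246 from those with vehicle, and the second (12.5%) separated ATF3-OE from empty-vector cells. The labels do not say that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

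ATF3 (ENSG00000162772, GRCh38 chromosome 1, 212565334 to 212620777, plus strand) was present at 6.35 ± 0.256 FPKM in Control (mean and SD, n = 3), 24.4 ± 1.55 with APR-246, 56.7 ± 3.27 in ATF3-OE and 84.4 ± 1.90 in ATF3-OE+APR-246. Levels below are likewise means of 3 libraries. ATF3-OE cells thus held 8.63-fold more than Control (log2 3.11, SE 0.06, edgeR adjusted p = 4.5e-12), and APR-246 raised ATF3 4.32-fold in empty-vector cells (log2 2.11, SE 0.06, edgeR adjusted p = 2.97e-11). The counts do not separate transcripts of the vector from those of the cell's own ATF3 gene. SLC7A11 (ENSG00000151012, chromosome 4, 138164097 to 138242349, minus strand) stood at 11.3 ± 2.22 FPKM in Control, 25.2 ± 1.51 with APR-246, 4.53 ± 1.17 in ATF3-OE and 17.9 ± 1.92 in ATF3-OE+APR-246. It was 2.56-fold lower in ATF3-OE than in Control (log2 -1.36, SE 0.16, edgeR adjusted p = 8.77e-05) and rose with APR-246 in both cell lines, by log2 1.33 (SE 0.16, edgeR adjusted p = 1.31e-05) in empty-vector and 2.14 (SE 0.17, edgeR adjusted p = 2.99e-07) in ATF3-OE cells. Under APR-246 the difference between ATF3-OE and empty-vector cells was log2 -0.55 (SE 0.16, edgeR adjusted p = 0.0306). That call was lost in 8 of 19 other settings, over which the adjusted p ran from 0.000836 to 0.161. Among them were the runs without APR-246 replicate 1 (log2 -0.55) or 2 (-0.53) and without ATF3-OE+APR-246 replicate 2 (-0.54) or 3 (-0.51).

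**Figure D1:**
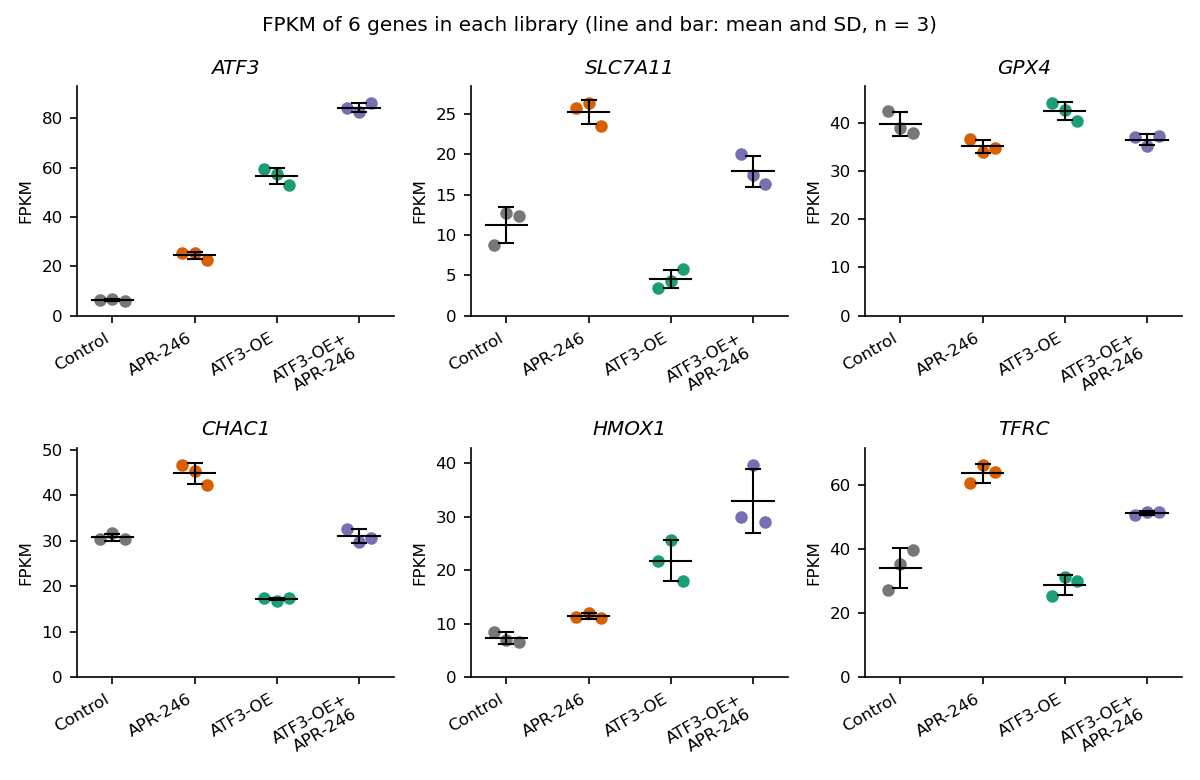
FPKM of 6 genes (y axes, from 0) in the 12 libraries by group (x axis); points are libraries, and lines with bars are means and SD of 3 libraries. ATF3 runs from 6.35 FPKM in Control to 84.4 in ATF3-OE+APR-246, and SLC7A11 from 4.53 in ATF3-OE to 25.2 with APR-246.

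In empty-vector cells the heat shock list had the highest median change with APR-246 of the 21 lists. HSPA1A, an inducible cytosolic chaperone of the HSP70 family, went from 4.76 to 953 FPKM (log2 7.81, SE 0.13), HSPA1B from 6.65 to 1157, and the co-chaperone DNAJB1 from 8.88 to 114 (log2 3.85, SE 0.06). HSPA1A and HSPA1B are near-identical copies, so the split of reads between them is uncertain. HSPA6, another HSP70 gene, rose from 0.00766 to 5.09 FPKM, the Control level resting on 5 counts in 1 library. Of 24 tested targets of HSF1, the main heat shock transcription factor, 23 rose and none fell (23 and 0 adjusted over the list alone), with a median log2 change of 2.18 (camera adjusted p = 5.67e-138, and adjusted p = 0.000198 with an estimated correlation). The member that did not pass was CRYAB, with at most 8 counts in any of these 6 libraries.

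APR-246 also raised targets of NRF2, the regulator of the response to electrophiles and oxidants. Of 28 tested members 24 rose and 1 fell, also adjusted over the list alone, with a median log2 change of 0.76 (camera adjusted p = 2.85e-20, and adjusted p = 0.00124 with an estimated correlation). GCLM, a subunit of the enzyme that starts glutathione synthesis, rose 3.01-fold (log2 1.59, SE 0.07) and TXNRD1, thioredoxin reductase, 2.79-fold (log2 1.48, SE 0.04). HMOX1, heme oxygenase, rose by log2 0.82 (SE 0.14). Among 43 targets of ATF4 and the integrated stress response, 22 rose, 9 fell and 12 did not pass (22 and 9 adjusted over the list alone). PPP1R15A, which directs dephosphorylation of eIF2alpha, rose by log2 2.11 (SE 0.07), SESN2 by 1.57 (SE 0.06) and CHAC1, which degrades glutathione, by 0.71 (SE 0.05). Those that fell include the aminoacyl-tRNA synthetase AARS1 (log2 -0.49) and the glycine transporter SLC6A9 (-1.09), both named after their values were seen. The list's call at the preset correlation (camera adjusted p = 1.33e-07) was lost in 2 of 19 other settings, among them an estimated correlation (adjusted p = 0.163).

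Of 26 suppressors of ferroptosis 14 rose and 4 fell (14 and 4 adjusted over the list alone), with a median log2 change of 0.34 (camera adjusted p = 3.35e-06, and adjusted p = 0.0122 with an estimated correlation). SLC7A11, GCLM and TXNRD1 were among those that rose. All of them are also members of the NRF2 list, so these lists are not separate observations. GPX4, the peroxidase that reduces lipid hydroperoxides, stood at 39.8 FPKM in Control and 35.1 with APR-246 and did not pass the test (log2 -0.01, SE 0.06). The call of GPX4 depends on the setting: it passed as lower in 6 of 19 other settings, each of them on FPKM and 1 of these quantile normalized, and the 19 gave values from log2 -0.18 to 0.05. Of 21 drivers and markers of ferroptosis 11 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.0073, and adjusted p = 0.0405 with an estimated correlation). TFRC, the transferrin receptor, rose 2.10-fold (log2 1.07, SE 0.10). The list's median was 0.25 and its mean -0.06. The mean includes ALOX12B, which had 0 counts in the 3 APR-246 libraries and at most 17 in a Control library. PTGS2, at 0.288 and 0.348 FPKM, did not pass.

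Among genes of the endoplasmic reticulum chaperone and unfolded protein response list, 11 of 19 rose and none fell (14 and 0 adjusted over the list alone; camera adjusted p = 4.89e-05, and adjusted p = 0.0405 with an estimated correlation), with XBP1 up by log2 0.98 (SE 0.04). Of 21 genes of the G2/M phase 17 rose and 1 fell (18 and 1 adjusted over the list alone; camera adjusted p = 1.81e-08, and adjusted p = 0.0114 with an estimated correlation), AURKA by log2 0.79 (SE 0.04) and BIRC5 by 0.78 (SE 0.04). In the S phase list 5 of 20 rose and 11 fell (camera adjusted p = 0.0855), with PCNA at log2 -0.62 (SE 0.04). That list passed in 6 of 19 other settings, its median running from -0.31 to -0.11 over the 19. Of 31 p53 targets 9 rose and 11 fell (camera adjusted p = 0.378), and CDKN1A did not pass (log2 -0.09, SE 0.04), though it did in 7 of 19 other settings.

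Further lists passed for APR-246 against Control at the preset correlation and not with an estimated one. They are glutathione and cysteine metabolism (13 of 28 higher, 6 lower, camera adjusted p = 0.0208), iron handling (8 of 15 higher, 4 lower, camera adjusted p = 0.00942), autophagy (7 of 16 higher, 4 lower, camera adjusted p = 0.0257) and cholesterol synthesis (5 of 20 higher, 9 lower, camera adjusted p = 0.043). Their calls were lost in 9, 8, 9 and 5 of 19 other settings, for cholesterol synthesis among them without APR-246 replicate 1 (median -0.10) or Control replicate 3 (-0.10), and the median took both signs over the settings for glutathione metabolism and autophagy. Of 7 tested markers of other cell types 5 were lower and none higher, with a median of -1.63 (camera adjusted p = 0.0447, and adjusted p = 0.131 with an estimated correlation), a call lost in 3 of 12 other settings, among them without Control replicate 1 (median -1.65). CD68, at 66.6 and 37.1 FPKM, was lower by log2 -0.67 (SE 0.08). Other members, such as VWF and CDH5, were too weak for the FPKM filter. Genes below 3 CPM (counts scaled to library size) fell in general with the drug, with a median log2 change of -0.43. The markers were not compared with genes of like abundance. The hypoxia and glycolysis list (6 of 15 higher, 6 lower, camera adjusted p = 0.858), the matrix list (6 of 24 higher, 10 lower, camera adjusted p = 0.349) and the AP-1 list (7 of 17 higher, 7 lower, camera adjusted p = 0.53) did not pass. The AP-1 list had a median of -0.15 and a mean of 1.13.

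Some inflammatory genes were lower with APR-246. IL1B dropped from 17.8 to 0.997 FPKM (15.7-fold, log2 -3.97, SE 0.22), and of 13 genes of the NF-kB and cytokine list 7 fell, 3 rose and 3 did not pass (camera adjusted p = 0.00455, and adjusted p = 0.101 with an estimated correlation). The list's call was lost in 5 of 19 other settings. Of 19 interferon-stimulated genes 8 fell and none rose (camera adjusted p = 0.0377, and adjusted p = 0.135 with an estimated correlation), a call lost in 7 of 18 other settings, among them without APR-246 replicate 3 (median -0.56). Members such as IFIH1 and OAS1 were also too weak for the FPKM filter. This list too was not set apart from the general fall of genes below 3 CPM (median log2 -0.43). The clock regulators NR1D1 (6.82-fold) and BHLHE40 (4.63-fold) were among the largest falls, and EGR1 (from 0.683 to 54.5 FPKM) and FOS (from 0.411 to 10.9) among the largest rises. The 4 tested genes of the metallothionein and zinc list fell, among them SLC30A1, a zinc exporter (log2 -1.76, SE 0.10). Too few members were left for a list test.

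Over all tested genes, 4465 were higher and 4556 lower with APR-246, 581 and 1568 of them by at least 2-fold. Of the fixed lists, 15 of 20 passed at the preset correlation and 6 with an estimated one. Genes of the mitochondrial genome, a sign of RNA quality, held 3.50% of counts with APR-246 and 4.38% in Control, and 5 of 13 fell, with MT-ND6 at log2 -0.82 (SE 0.06). The list's call (camera adjusted p = 0.0447, and adjusted p = 0.571 with an estimated correlation) was lost in 8 of 19 other settings, among them the runs without APR-246 replicate 2 (median -0.04) or 3 (-0.08) and without Control replicate 1 (-0.10) or 3 (-0.08).

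**Figure D2:**
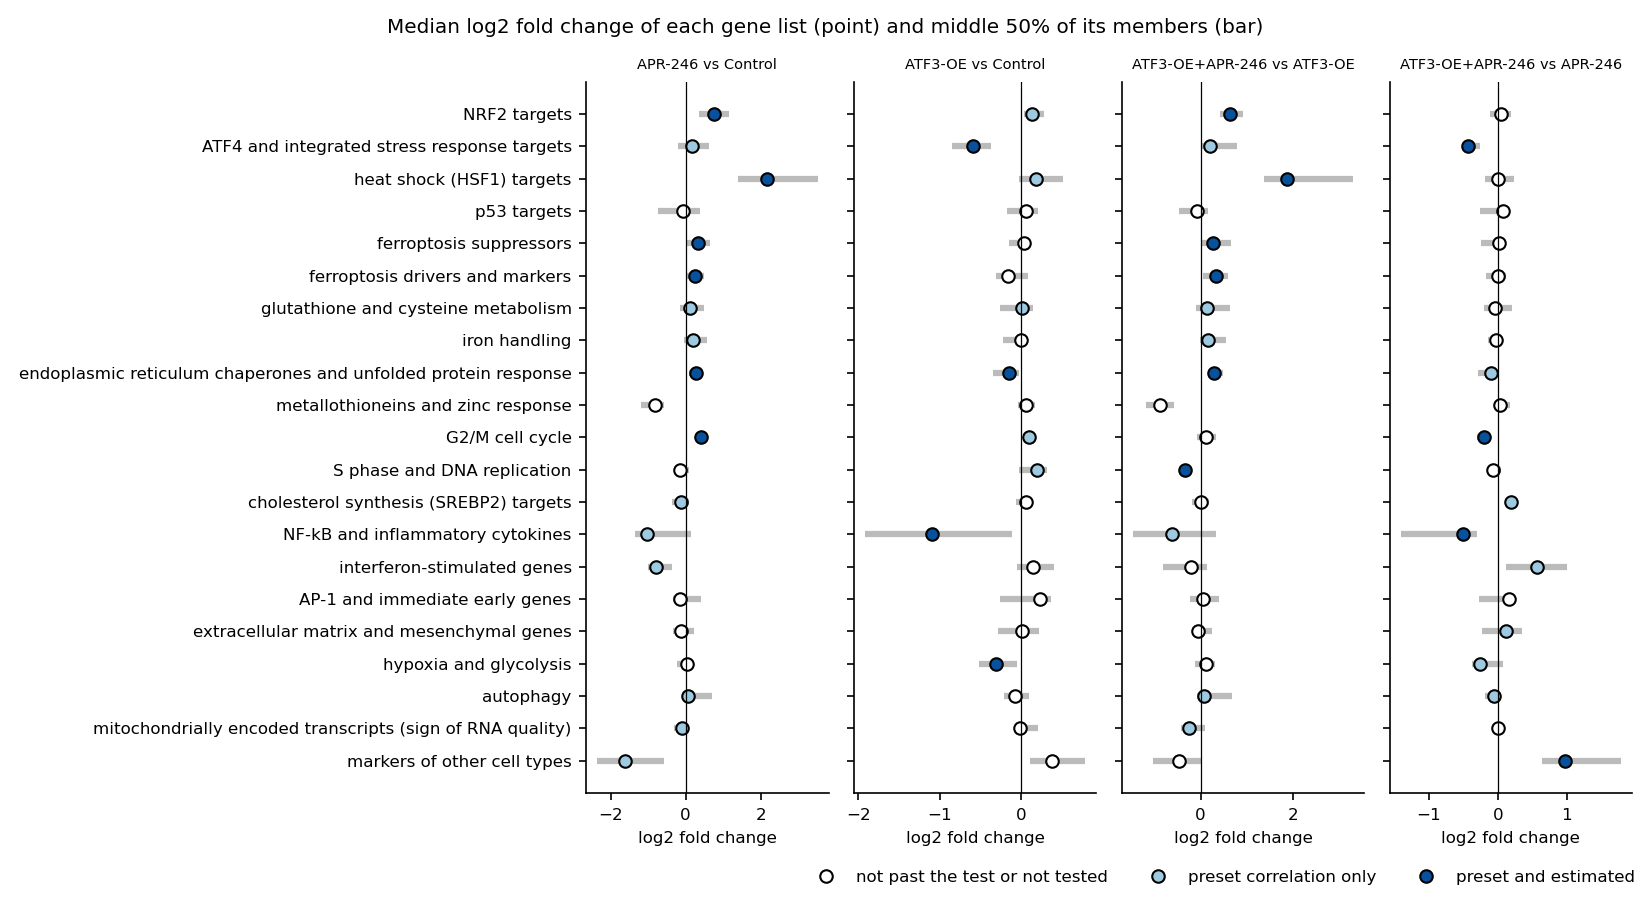
Median log2 fold change (x axis) of the members of each gene list (y axis) in the 4 comparisons of groups; bars span the middle 50% of members, and fill shows whether camera passed at the preset correlation or also at an estimated one. The heat shock list has a median of 2.18 for APR-246 against Control, and the ATF4 list -0.59 for ATF3-OE against Control.

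Without the drug, most of the ATF4 list was lower in ATF3-OE than in empty-vector cells. Of 43 targets of ATF4 and the integrated stress response 37 fell and none rose (39 and 0 adjusted over the list alone), with a median log2 change of -0.59 (camera adjusted p = 9.16e-86, and adjusted p = 0.00331 with an estimated correlation). TRIB3, a pseudokinase, was 2.98-fold lower (log2 -1.57, SE 0.07), INHBE 2.97-fold (-1.57, SE 0.09), CHAC1 1.85-fold (-0.89, SE 0.05) and GDF15 2.19-fold (-1.13, SE 0.06). SLC7A11 is a member of this list and of the NRF2 list. In the NRF2 list 5 of 28 rose and 1 fell (11 and 3 adjusted over the list alone; camera adjusted p = 0.00442, and adjusted p = 0.139 with an estimated correlation), with HMOX1 at 7.30 FPKM in Control and 21.8 in ATF3-OE (2.89-fold, log2 1.53, SE 0.14).

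Some inflammatory genes were lower in ATF3-OE too. IL1B was 7.34-fold (log2 -2.88, SE 0.21) and IL1A 7.95-fold lower (-2.99, SE 0.40), and 7 of 13 genes of the NF-kB and cytokine list fell with none higher (10 and 1 adjusted over the list alone; camera adjusted p = 9.73e-13, and adjusted p = 0.00717 with an estimated correlation). Genes of the endoplasmic reticulum list fell in 10 of 19 cases (camera adjusted p = 7.51e-09, and adjusted p = 0.0128 with an estimated correlation), XBP1 by log2 -0.61 (SE 0.04). In the hypoxia and glycolysis list 9 of 15 fell and 2 rose (camera adjusted p = 1.76e-13, and adjusted p = 0.0199 with an estimated correlation), CA9, a carbonic anhydrase, 2.31-fold and VEGFA 1.83-fold. Matrix genes that were lower include tenascin C, TNC (4.28-fold), and the collagenase MMP1 (3.08-fold). The matrix list as a whole did not pass, with 5 of 24 higher and 8 lower (camera adjusted p = 0.191), though it did without ATF3-OE replicate 1 (median -0.04).

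Higher in ATF3-OE were 12 of 20 S phase genes with none lower (camera adjusted p = 6.1e-07, and adjusted p = 0.0733 with an estimated correlation), for example GINS1 (1.47-fold), and 11 of 24 heat shock genes with 1 lower (camera adjusted p = 4.7e-10, and adjusted p = 0.0794 with an estimated correlation). HSPA1A stood at 18.1 FPKM against 4.76 in Control (log2 1.88, SE 0.11). RGS4, a regulator of G protein signaling, was 3.38-fold higher. In the G2/M list 3 of 21 were higher and none lower (camera adjusted p = 0.0304, and adjusted p = 0.189 with an estimated correlation). That call was lost in 4 of 19 other settings, among them without ATF3-OE replicate 2 (median 0.07) or 3 (0.05) and without Control replicate 1 (0.06). The ferroptosis suppressors did not pass as a list, with 2 of 26 higher and 5 lower (camera adjusted p = 0.463), nor did the drivers and markers, with 3 of 21 higher and 5 lower (camera adjusted p = 0.299). GPX4 (log2 0.05, SE 0.06), TFRC (-0.29, SE 0.10) and CDKN1A (0.12, SE 0.04) did not pass. TFRC did without Control replicate 1 (-0.42), and CDKN1A did in 7 of 19 other settings. PTGS2, at 0.288 and 0.0880 FPKM, was lower by log2 -1.75 (SE 0.44, edgeR adjusted p = 0.0169). The p53 list had a median of 0.05 and a mean near 0 with a camera direction of down, and did not pass (camera adjusted p = 0.0972), though it did without ATF3-OE replicate 1 (median 0.06) or Control replicate 3 (0.02). The AP-1 list likewise had a median of 0.23 with a direction of down (camera adjusted p = 0.258) and passed without Control replicate 3 (median 0.18). The glutathione list had a median of 0.01, a mean of -0.13 and a direction of down (camera adjusted p = 0.0362, and adjusted p = 0.202 with an estimated correlation), a call lost in 11 of 19 other settings, among them without Control replicate 1 (median -0.003).

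In total 1340 genes were higher and 1312 lower in ATF3-OE than in Control, 126 and 154 of them by at least 2-fold, and 9 of 20 lists passed at the preset correlation and 4 with an estimated one. The count of higher genes fell to 861 without Control replicate 2, 866 without ATF3-OE replicate 1 and 891 without Control replicate 3. It was at most 1081 in any run that left out 1 library, and each such run has fewer libraries.

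In ATF3-OE cells APR-246 again raised heat shock genes, 23 of 24 with none lower and a median log2 change of 1.87 (camera adjusted p = 3.91e-141, and adjusted p = 8.09e-05 with an estimated correlation). HSPA1A went from 18.1 to 1105 FPKM (log2 6.09, SE 0.12) and EGR1 from 0.913 to 63.7. Of 28 NRF2 targets 23 rose and 1 fell (24 and 1 adjusted over the list alone), with a median of 0.63 (camera adjusted p = 2.67e-19, and adjusted p = 0.00136 with an estimated correlation), SLC7A11 4.42-fold. Of the ATF4 list 25 of 43 rose and 5 fell (25 and 7 adjusted over the list alone; camera adjusted p = 3.21e-16, and adjusted p = 0.0602 with an estimated correlation). DDIT3, which encodes CHOP, rose 6.04-fold (log2 2.59, SE 0.08) and CHAC1 2.01-fold (1.01, SE 0.05). Suppressors of ferroptosis rose in 15 of 26 cases with 3 lower (camera adjusted p = 1.45e-07, and adjusted p = 0.00772 with an estimated correlation), and drivers and markers in 11 of 21 with 1 lower (camera adjusted p = 0.000895, and adjusted p = 0.017 with an estimated correlation), among them ACSL4, which activates polyunsaturated fatty acids (2.09-fold), and TFRC (1.98-fold).

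Endoplasmic reticulum genes rose in 17 of 19 cases with none lower (camera adjusted p = 2.61e-08, and adjusted p = 0.0125 with an estimated correlation). S phase genes fell in 16 of 20 cases with 1 higher (camera adjusted p = 2.61e-08, and adjusted p = 0.0389 with an estimated correlation), PCNA by log2 -0.87 (SE 0.04). In the G2/M list 8 of 21 rose and 2 fell (camera adjusted p = 0.117). IL1B was 8.57-fold lower with the drug and TNFAIP3, an inhibitor of NF-kB signaling, 7.21-fold, while the NF-kB list of 13 had 6 lower and 3 higher (camera adjusted p = 0.0114, and adjusted p = 0.181 with an estimated correlation). GPX4 did not pass (log2 -0.06, SE 0.06), but it passed as lower in 6 of 19 other settings, each of them on FPKM, and the 19 gave values from log2 -0.22 to -0.01. Genes of the mitochondrial genome held 4.47% of counts in ATF3-OE and 3.66% in ATF3-OE+APR-246. Of 13, 7 fell and 2 rose, with a median of -0.26 (camera adjusted p = 0.00667, and adjusted p = 0.419 with an estimated correlation) and MT-ND6 at log2 -1.10 (SE 0.06), a list call lost in 6 of 19 other settings. Over all genes 4202 were higher and 3852 lower, 565 and 1104 of them by at least 2-fold, and 12 of 20 lists passed at the preset correlation and 6 with an estimated one.

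Under APR-246, ATF3-OE cells differed from empty-vector cells most evenly in the ATF4 list. Of 43 members 36 were lower and none higher, also adjusted over the list alone, with a median of -0.43 (camera adjusted p = 3.08e-50, and adjusted p = 0.0138 with an estimated correlation). INHBE was 2.61-fold lower (log2 -1.39, SE 0.09), GDF15 2.21-fold (-1.14, SE 0.06), and CHAC1 was at log2 -0.59 (SE 0.05). G2/M genes were lower in 13 of 21 cases with none higher (15 and 0 adjusted over the list alone; camera adjusted p = 9.47e-09, and adjusted p = 0.0138 with an estimated correlation), AURKA by log2 -0.43 (SE 0.04). NF-kB and cytokine genes were lower in 7 of 13 cases (camera adjusted p = 1.55e-08, and adjusted p = 0.0205 with an estimated correlation), IL1B 4.02-fold and IL1A 5.63-fold. HMOX1 remained higher, 11.5 against 32.9 FPKM (2.76-fold), as did RGS4 (log2 2.38, SE 0.08). Of the 6 named genes with the largest rises here, 4 were transcripts of the ribosomal RNA repeat, in libraries made from poly(A) RNA: RNA5-8SN2 (3.55 against 23.2 FPKM, log2 2.64, SE 0.24), 5_8S_rRNA (log2 2.49, SE 0.22), RNA5-8SN1 (log2 2.48, SE 0.27) and MIR3648-1 (log2 2.34, SE 0.22). All 4 passed in each of 19 other settings, but as transcripts of a repeated unit they are not 4 separate observations. RNA5-8SN2 was at 2.37 FPKM in Control and 3.41 in ATF3-OE, so the high level was in the ATF3-OE+APR-246 libraries only. The heat shock list did not pass, with 5 of 24 higher and 6 lower (camera adjusted p = 0.683).

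Cholesterol synthesis genes were higher in 9 of 20 cases with 1 lower (camera adjusted p = 7.97e-05, and adjusted p = 0.0815 with an estimated correlation), HMGCS1 by log2 0.43 (SE 0.06). Of 19 interferon-stimulated genes 5 were higher and none lower (camera adjusted p = 0.00269, and adjusted p = 0.0616 with an estimated correlation). Suppressors of ferroptosis, with 3 of 26 higher and 6 lower, and drivers and markers, with 3 of 21 higher and 5 lower, did not pass (camera adjusted p = 0.632 and 0.683). TFRC was lower by log2 -0.37 (SE 0.10, edgeR adjusted p = 0.028), a call that was lost in 11 of 19 other settings, over which the adjusted p ran from 0.000195 to 0.223. Among them were the runs without APR-246 replicate 2 (-0.35) or 3 (-0.39) and without ATF3-OE+APR-246 replicate 1 (-0.38), 2 (-0.39) or 3 (-0.39). PTGS2, at 0.348 and 0.119 FPKM, was lower by log2 -1.59 (SE 0.43, edgeR adjusted p = 0.0227) and lost its call in 5 of 13 settings: without APR-246 replicate 1 (-1.56) or 3 (-1.56) and without ATF3-OE+APR-246 replicate 1 (-1.65), 2 (log2 -1.499) or 3 (-1.67). CDKN1A was higher by log2 0.15 (SE 0.04, edgeR adjusted p = 0.0259) and lost its call in 6 of 19, among them without APR-246 replicate 1 (0.12), 2 (0.13) or 3 (0.13) and without ATF3-OE+APR-246 replicate 2 (0.11) or 3 (0.12).

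Markers of other cell types were higher in 4 of 7 tested genes (camera adjusted p = 0.00165, and adjusted p = 0.0454 with an estimated correlation), all at low levels except CD68: CDH5 stood at 0.0206 FPKM with APR-246 and 0.199 in ATF3-OE+APR-246. In total 1527 genes were higher and 1530 lower, 275 and 120 of them by at least 2-fold, and 10 of 20 lists passed at the preset correlation and 4 with an estimated one. The count of higher genes fell to 943 without ATF3-OE+APR-246 replicate 2 and was at most 1139 in any run that left out 1 library.

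The interaction tests whether the drug's effect differed between ATF3-OE and empty-vector cells. It called 141 genes with a higher and 171 with a lower effect in ATF3-OE cells, 1.56% of those tested. Both counts were lower in every run that left out 1 library, with at most 119 higher and 141 lower effects. Each such run has fewer libraries and was filtered anew, so a lower count does not by itself point to the library left out. The count of higher effects was 51 without APR-246 replicate 1, 65 without replicate 2, 52 without ATF3-OE replicate 2, 83 without replicate 3, 64, 68 and 60 without ATF3-OE+APR-246 replicates 1, 2 and 3, and 55 and 85 without Control replicates 2 and 3. The count of lower effects was 43, 48 and 111 without APR-246 replicates 1, 2 and 3, 94 and 48 without ATF3-OE replicates 1 and 2, 53, 60 and 63 without ATF3-OE+APR-246 replicates 1, 2 and 3, and 58 and 77 without Control replicates 2 and 3. ATF3 itself rose by a smaller ratio with the drug in ATF3-OE cells (interaction log2 -1.38, SE 0.08, edgeR adjusted p = 5.31e-06), as did HSPA1A (-1.72, SE 0.14) and HSPA1B (-1.62, SE 0.13). For ATF3 the vehicle level was higher in ATF3-OE cells, and the levels went from 6.35 to 24.4 FPKM in empty-vector and from 56.7 to 84.4 in ATF3-OE cells, which is no smaller a rise in FPKM. For HSPA1A and HSPA1B the vehicle levels differed by a larger ratio (4.76 and 18.1 FPKM for HSPA1A) than the levels with the drug (953 and 1105), though by fewer FPKM. SLC7A11 had an interaction of log2 0.81 (SE 0.22) that did not pass (edgeR adjusted p = 0.0985), though it did without ATF3-OE replicate 3 (1.02) and without Control replicate 1 (0.96). CHAC1 was at 0.30 (SE 0.07, edgeR adjusted p = 0.0546) and passed in 7 of 24 other settings, while GPX4, HMOX1, CDKN1A, PTGS2 and TFRC did not pass. Of the lists, G2/M (7 of 21 lower), heat shock (5 of 24 lower) and S phase (4 of 20 lower) had a negative interaction, with none higher. Their camera adjusted p = 0.000898, 0.0477 and 0.0177 with an estimated correlation. The drug's rise was smaller in ATF3-OE than in empty-vector cells for G2/M (medians 0.12 and 0.40) and heat shock (1.87 and 2.18). For S phase the drug's fall was larger in ATF3-OE cells (-0.33 and -0.14). With vehicle, ATF3-OE differed from empty-vector cells by medians of 0.18 for heat shock and 0.195 for S phase. With APR-246 the medians were 0.0042 and -0.07. Another 8 lists passed at the preset correlation only.

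**Figure D3:**
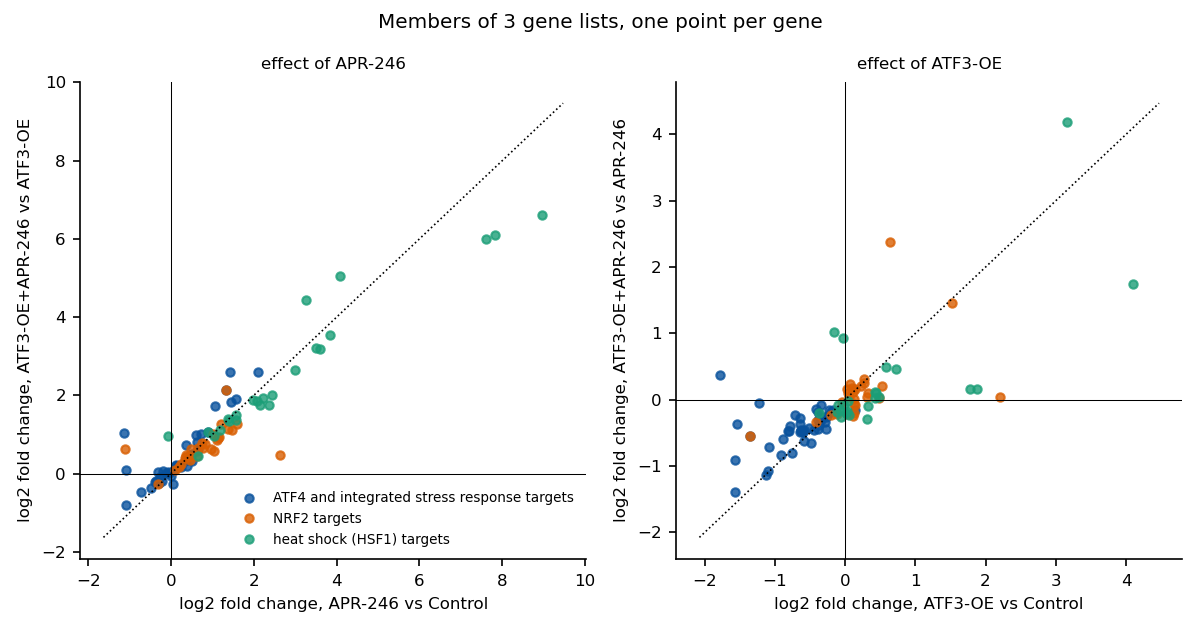
Log2 fold change of each member of 3 gene lists, for the drug in empty-vector (x) and ATF3-OE cells (y) on the left, and for ATF3-OE with vehicle (x) and with APR-246 (y) on the right; the dotted line marks equal values. NRF2 and heat shock genes lie mostly above 0 on the left (23 of 24 heat shock genes rose in each cell line), and ATF4 targets mostly below 0 on the right.

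Across the 19970 genes, which are not independent replicates, the drug's log2 fold changes in the 2 cell lines correlated at Pearson r = 0.570 (Spearman 0.728). Among the 10713 genes with at least 5 CPM (counts scaled to library size), r was 0.827. Called genes overlapped, with 3491 higher in both against 940 for independent lists and 3011 lower in both against 879. The effect of ATF3-OE with vehicle and with APR-246 correlated at r = 0.223 (Spearman 0.346), and at Pearson r = 0.448 among the genes with at least 5 CPM, with 650 genes higher in both against 103 and 744 lower in both against 101. With 1 library left out, r over all tested genes was 0.460 to 0.486 for the drug and 0.134 to 0.163 for ATF3-OE. The drug and ATF3-OE comparisons with Control share the 3 Control libraries. They correlated at r = 0.250 (Spearman 0.140), and at 0.239 to 0.457 when 1 library was left out. Unchanged groups simulated against those libraries gave 0.503. Sharing a reference group brings about such a value without any effect, so a lower r is no sign of less agreement than by chance. The covariance was 0.182 against a simulated mean of 0.156 and a simulated highest value of 0.1665. Among the genes with at least 5 CPM r was 0.1995 against 0.494 simulated, and the covariance was 0.0327 against a simulated mean of 0.0105 and a simulated highest value of 0.0315. Of their calls 530 were higher in both against 300 for independent lists, 441 lower in both against 299, 454 higher with the drug but lower in ATF3-OE against 293, and 408 lower with the drug but higher in ATF3-OE against 306, so each of the 4 combinations exceeded the value for independent lists. Part of the excess in the same direction may come from the shared libraries, which are too few to split. Chance shared through them moves both comparisons the same way, so it would not raise the opposite combinations. The value for independent lists, here and in the overlaps above, takes every gene as equally likely to be called. An excess over it is therefore description only.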

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

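The test of scaling on the ATF4 targets, the resampling of genes and the splits within each treatment were chosen after the result was seen, and the other tests in this part were set out before their results. The values of the interaction given first, and BCAP29, drew attention because the drug's effect differed between ATF3-OE and empty-vector cells in that test. The lower ATF4 targets and the lower weakly expressed genes at the end were noticed in the comparisons with Control.

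The interaction called 141 genes with a higher and 171 with a lower drug effect in ATF3-OE cells. Of 60 splits of the 12 libraries into groups of 3, the real one included, 3 gave as many as the real 312 genes, and the highest other count was 9841. Such splits can set drug against vehicle libraries within the interaction, so a count that large points to the structure of the samples, their division by the drug. For lists, 7 of 60 splits gave as many as the real 11, the highest other being 15. These splits therefore do not measure chance for the interaction. In the 2-group comparisons the 6 libraries make only 10 splits, too few for a share under 0.05. The real counts and highest others were 9021 genes and 1 for APR-246 against Control, 2652 and 2 for ATF3-OE against Control, 8054 and 0 for ATF3-OE+APR-246 against ATF3-OE, and 3057 and 2 for ATF3-OE+APR-246 against APR-246. For lists they were 15 and 8, 9 and 7, 12 and 9, and 10 and 6, so other splits also passed several lists at the preset correlation. Among the correlations of fold changes, 1 of 60 splits, the real one, reached that of the drug effect in the 2 cell lines (0.570, highest other 0.393). No other split tried came as high. Shuffling libraries cannot address chance between cultures or cell pools, so chance is not excluded. For the ATF3 effect with and without drug (7 of 60, highest other 0.404) and the comparisons that share Control (57 of 60, highest other 0.792) these splits again carry the drug's effect and decide nothing. With the genotypes shuffled only within each treatment, 1 of 60 splits, the real one, reached the correlation of the ATF3 effect (0.223, highest other 0.104). The same limit holds for these splits.

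The named interaction values on the log2 scale were 2.67 for BCAP29, 2.503 for MIR3648-2, 2.497 for MIR3648-1, 2.27 for 5_8S_rRNA, 2.15 for RNA5-8SN2, -1.88 for MT-TV, -1.72 for HSPA1A, -1.62 for HSPA1B, -1.41 for DUS4L-BCAP29 and -1.38 for ATF3. MIR3648-2, MIR3648-1, 5_8S_rRNA and RNA5-8SN2 are transcripts of the ribosomal RNA repeat, in libraries made from poly(A) RNA, and not separate observations. The medians of the lists that passed at the preset correlation were -0.0272 for NRF2, 0.11 for ATF4, -0.21 for heat shock, 0.08 for the endoplasmic reticulum, -0.27 for G2/M, -0.24 for S phase, 0.18 for cholesterol synthesis, 0.33 for interferon, 0.16 for matrix, 0.10 for hypoxia and 0.66 for markers of other cell types. Leaving out 1 library ended the call of 4 of these lists. For NRF2 this was without APR-246 replicate 2 (-0.0417), ATF3-OE replicate 1 (-0.084) or Control replicate 2 (-0.0154). For the endoplasmic reticulum it was without APR-246 replicate 1 (0.0669) or 3 (0.0705), ATF3-OE replicate 3 (0.073), ATF3-OE+APR-246 replicate 3 (0.074) or Control replicate 3 (0.069). For interferon it was without APR-246 replicate 3 (0.29), ATF3-OE replicate 1 (0.27) or 3 (0.28), ATF3-OE+APR-246 replicate 2 (0.31) or 3 (0.30) or Control replicate 1 (0.20). For markers of other cell types it was without Control replicate 1 (0.36).

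BCAP29 and the read-through gene DUS4L-BCAP29 move in opposite directions in the interaction while lying over the same exons. BCAP29 had mean counts of 3706 in Control, 825 with APR-246, 3641 in ATF3-OE and 5152 in ATF3-OE+APR-246, where DUS4L-BCAP29 had 2285, 6880, 3552 and 3866. With the counts of BCAP29, DUS4L-BCAP29 and DUS4L summed, the interaction was 0.11 (SE 0.10, edgeR adjusted p = 0.695). A candidate explanation is that reads of this locus were assigned to different overlapping genes in different libraries. A change in which transcript is made stays open, and no biological explanation was tested.

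The lower ATF4 targets in ATF3-OE cells had a list median of -0.59. The values argue against scaling between libraries as the cause, since the highest median over 4 other scalings was -0.51. After removing a trend on GC content, gene length and abundance the median was -0.53, and 0 of 10000 random lists of like abundance had a median as low (their middle 95% ran from -0.09 to 0.02). The same direction appears under APR-246 in libraries that share none with this comparison. A direct or indirect effect of ATF3 on these genes may underlie it, a hypothesis that came from these data and was not tested. A difference between the selected cell pools other than ATF3 stays open.

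Weakly expressed genes fell with APR-246. The 8379 genes below 3 CPM had a median log2 change of -0.43 against 0.04 for the others, and 1495 of them were lower and 400 higher. Without 33 heat shock and most-gaining genes, which held 2.76% of counts in Control and 6.20% with the drug, the median was -0.426. TMM scaling trims the genes with the most extreme changes in either run, so taking them out could hardly move the median. That run therefore does not decide whether a few abundant genes are the cause. With every library thinned to the lowest total the median was -0.434, which argues against depth. Removing a trend on GC content and length moved the median of the genes with a reference transcript from -0.42 to -0.26 (middle 95% over 200 resamples of the genes, -0.28 to -0.23), so GC content or length may account for a part. Whether they account for the whole is not decided. The trend rests on the longest transcript of each gene, and resampling genes does not measure the error of that choice. Lower transcription of weak genes, RNA breakdown in dying cells and other effects of the drug stay open, and none was tested.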

How the results depend on the processing

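The runs of counts divided by 4 and of correlations on a fixed set of genes were chosen after the data were seen. Limma with trend on FPKM was the planned test for a table without raw counts. No named gene or correlation of fold changes took the opposite sign with a call under any alternative. The medians of 3 lists did so when 1 library was left out, each near 0 and with the direction of the test unchanged. For ATF3-OE against Control they are the matrix list (median 0.01), at -0.04 without ATF3-OE replicate 1, and the glutathione list (median 0.01), at -0.05 without ATF3-OE replicate 1, -0.03 without replicate 3, -0.08 without Control replicate 2 and -0.02 without replicate 3. For ATF3-OE+APR-246 against APR-246 the p53 list (median 0.07) was at -0.0026 without APR-246 replicate 1 and -0.016 without ATF3-OE+APR-246 replicate 2. The direction and call of ATF3 held in every comparison and alternative tried, as did SLC7A11 for the drug in both cell lines and for ATF3-OE against Control. SLC7A11 in ATF3-OE+APR-246 against APR-246 lost its call with limma on FPKM with no filter (-0.47), no trend (-0.47) and a pseudocount of 0.1 (-0.49) and with no filter on low counts (-0.57), and ran from -0.66 to -0.51 when 1 library was left out, losing it without APR-246 replicate 1 (-0.55) or 2 (-0.53) and without ATF3-OE+APR-246 replicate 2 (-0.54) or 3 (-0.51). Its interaction ran from 0.66 to 1.02 and passed without ATF3-OE replicate 3 (1.02) and without Control replicate 1 (0.96). With a term for the replicate block the counts were 4490 higher and 4459 lower for APR-246 against Control, 1326 and 1306 for ATF3-OE against Control, 4197 and 3775 for ATF3-OE+APR-246 against ATF3-OE, 1460 and 1530 for ATF3-OE+APR-246 against APR-246 and 109 and 128 for the interaction, with 15, 10, 12, 11 and 11 lists. Equal numbers did not pair libraries throughout: deviations correlated at a median of -0.01 over 18 pairs, and 5 of 12 libraries correlated best with their own number. The pairs ran from -0.26 to 0.37, the highest being replicate 1 of Control and of ATF3-OE.

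A minimum absolute log2 fold change of 1 left, higher and lower, 581 and 1568, 126 and 154, 565 and 1104, 275 and 120, and 35 and 8 in the same order of comparisons. The share of called genes that were higher was 49.5% for APR-246 against Control and 50.5% for ATF3-OE against Control with edgeR. With limma with trend on FPKM without scaling between libraries it was 34.9% and 66.2%, a run that also differs in the test and the genes tested. On FPKM, median-ratio scaling gives 57.1% and 49.4% and quantile normalization 48.8% and 54.1%. On the same 11902 genes, the median change of all genes for APR-246 against Control is -0.10 without scaling, 0.04 with median-ratio scaling and -0.0086 with quantile normalization. GPX4 is not past the threshold with median-ratio scaling (-0.0043), a run that differs from limma with trend in scaling only, but is with quantile normalization (-0.17). Missing scaling may thus account for its lower calls on unscaled FPKM. It does not account for the quantile normalized call, and the cause was not tested. Genes higher for APR-246 against Control were then 2687 with limma with trend, 2688 with a pseudocount of 0.1, 2674 with no trend, 2655 with no filter and 1998 at a minimum of 5 FPKM, and for ATF3-OE+APR-246 against ATF3-OE 2378, 2364, 2352, 2438 and 1748. Fewer genes are tested at a minimum of 5 FPKM (6872), and there 2729 were lower for APR-246 against Control, 783 for ATF3-OE against Control, 836 for ATF3-OE+APR-246 against APR-246 and 290 for the interaction. Genes lower for ATF3-OE+APR-246 against APR-246 were 974 with limma with trend, 990 with a pseudocount of 0.1, 910 with no trend and 744 with no filter on FPKM, which gave 5856 lower for ATF3-OE+APR-246 against ATF3-OE. Of the 9021 genes called for APR-246 against Control, 7194 were tested with limma with trend, 5763 of them called with the same sign and 2 with the opposite sign.

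The interaction depends most on the setting: 364 higher and 544 lower with the DESeq2 Wald test, 68 and 94 with no filter on low counts, 213 and 258 with limma with trend, and 275 lower with median-ratio scaling. Leaving out 1 library gave 51 (without APR-246 replicate 1) to 119 (without APR-246 replicate 3) higher and 43 (without APR-246 replicate 1) to 141 (without Control replicate 1) lower. It gave 861 to 1081 higher for ATF3-OE against Control (861 without Control replicate 2, 866 without ATF3-OE replicate 1, 891 without Control replicate 3) and 943 (without ATF3-OE+APR-246 replicate 2) to 1139 higher for ATF3-OE+APR-246 against APR-246. Each such run has fewer libraries. Over the named genes these runs left the result unchanged, passing or not, in 1310 cases, lost a call in 66 and gained 1 in 4. Over the lists the counts were 674 unchanged, passing or not, 30 lost and 16 gained.

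With an estimated inter-gene correlation 6, 4, 6, 4 and 3 lists passed in place of 15, 9, 12, 10 and 11. For APR-246 against Control 8 passed with median-ratio scaling and 6 with quantile normalization. For ATF3-OE+APR-246 against ATF3-OE 7 passed with limma with trend, no trend, a pseudocount of 0.1, median-ratio scaling and quantile normalization. For ATF3-OE+APR-246 against APR-246 6 passed at a minimum of 5 FPKM and with median-ratio scaling, and 5 with limma with trend, no trend, a pseudocount of 0.1 and quantile normalization.

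The correlation of the drug effect in the 2 cell lines was 0.760 with counts divided by 4, 0.542 with the DESeq2 Wald test, 0.203 with no filter on low counts and, with limma on FPKM, 0.876 with trend, 0.896 at a minimum of 5, 0.879 with median-ratio scaling, 0.873 with quantile normalization, 0.847 with a pseudocount of 0.1 and 0.840 with no filter. That of the ATF3 effect was 0.406 with counts divided by 4, 0.0489 with no filter on low counts and, on FPKM, 0.532 with trend, 0.579 at a minimum of 5, 0.535 with median-ratio scaling, 0.530 with quantile normalization, 0.468 with a pseudocount of 0.1 and 0.464 with no filter. Leaving out 1 library gave 0.460 to 0.486 for the drug effect and 0.134 to 0.163 for the ATF3 effect, all below the values on 12 libraries. The filter on counts keeps more weakly counted genes when a group has 2 libraries, and on the genes of the full run the ranges were 0.520 to 0.550 and 0.183 to 0.223, so the genes kept account for a part of that fall. The comparisons that share Control correlated at 0.239 to 0.457 when 1 library was left out. Other than where fewer genes or libraries or a different scaling are named, the cause was not tested.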

Other observations

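The pathway annotation in the deposited table was tested in the same way after the other results were seen, over 227 pathways with 15 to 300 tested genes. With APR-246 against Control 50 pathways passed at the preset correlation and 33 with an estimated one. Of the 50, all but ECM-receptor interaction and fat digestion and absorption were higher, among them oocyte meiosis and T cell receptor signaling. The test sets a pathway against all other tested genes, and genes below 3 CPM fell with the drug (median log2 -0.43). These pathways were not compared with genes of like abundance, so how far abundance accounts for their calls was not tested. Protein processing in the endoplasmic reticulum had 92 of 154 genes higher and 12 lower (adjusted p = 0.00335 with an estimated correlation), a set that includes heat shock genes. Genes of RNA handling were higher as well: 48 of 89 in the mRNA surveillance pathway with 6 lower (adjusted p = 0.00841), 62 of 102 in nucleocytoplasmic transport with 8 lower (adjusted p = 0.0385) and 61 of 131 in the spliceosome with 13 lower (adjusted p = 0.0385), each with an estimated correlation. Autophagy had 79 of 154 higher and 26 lower (adjusted p = 0.00472), ubiquitin-mediated proteolysis 69 of 135 higher and 23 lower (adjusted p = 0.00841), and the ferroptosis pathway 19 of 32 higher and 3 lower (adjusted p = 0.00975).

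In ATF3-OE cells the drug gave 42 pathways at the preset correlation and 15 with an estimated one, among them ferroptosis (19 of 32 higher, 3 lower, adjusted p = 0.00738 with an estimated correlation) and endocytosis (101 of 227 higher, 35 lower, adjusted p = 0.00321). Most of the 42 were higher here too, and they were likewise not compared with genes of like abundance. For ATF3-OE against Control 20 pathways passed at the preset correlation, for ATF3-OE+APR-246 against APR-246 13 and for the interaction 19, and in these 3 comparisons 0 passed with an estimated correlation. The ferroptosis pathway went down for ATF3-OE against Control, with 4 of 32 higher and 11 lower (camera adjusted p = 0.0362, and adjusted p = 0.184 with an estimated correlation).

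SLC7A11 is a member of both the ATF4 and the NRF2 list. For ATF3-OE against Control 22 of 28 NRF2 members did not pass, the list's median was 0.12 and its call was lost with an estimated correlation (adjusted p = 0.139), and the difference between the lists was not tested. Whether SLC7A11 goes with the ATF4 targets there was looked at after these values were seen, so the values below describe the pattern and do not test it. The median of the other 42 ATF4-list members was -0.59 and that of the NRF2 list without SLC7A11 0.13, while SLC7A11 changed by log2 -1.36, and 4 of the 42 were lower still. These values do not tell a fall of ATF4 activity from binding of ATF3 at the same genes.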
